A study of Mus musculus with 8 samples.

How the data were processed

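Capture Hi-C libraries of E12.5 limb buds from 8 mouse mutants were analysed, each with a raw and a balanced contact map (16 deposited maps). Per the submitters' processing notes the tools were Bowtie2 2.2.6 and Juicer and the genome build was mm9; read filters, duplicate removal and the mapping quality minimum are not given in the sources used here. The raw values are counts of read pairs per pair of 10 kb bins, as deposited by the authors. The balanced values (KR, Knight-Ruiz, named in the deposited files) are a signal made by the authors from those counts, with each library's total kept close to its raw total, so they are not scaled between libraries. They held 4 values that were not a number in ∆BorC1, 7 in ∆BorC1-4 and 1 in ∆CTCF.

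Depth ran from 3056502 to 9045698 raw contacts. Each genotype had 1 library, so no test was made. Shares have exact Clopper-Pearson 95% intervals, ratios of shares a log-normal 95% interval and contact numbers an exact Poisson interval, all of which cover counting error only and take read pairs as independent. The spread of the same measures at unedited flank positions, at least 300 kb outside Kcnj2 to Sox9, describes how libraries differ without an edit; it is not replicate error.

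Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A bin's coverage is its share of the library's raw contacts over the median share in libraries whose label does not name the same change. Bins under 0.5 of that median were called depleted. The rule for the boundary, bins depleted in all 3 ∆BorC libraries, gave 4 bins, of which 111390001 to 111400000 was nearly empty and was used. The bins at 111710001 and 111870001 are places where, by coverage, the comparators held other sequence. Coverage profiles were compared at the same position, shifted in steps of 0.5 kb and mirrored. This comparison was added after the data were seen. For the inversion fit, raw contacts at least 20 kb apart were modelled as Poisson with distance decay and bin coverage, on a 50 kb grid refined to 10 kb.

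The cross-boundary share is raw contacts between the interval from Kcnj2 to the boundary and that from the boundary to Sox9, as a percent of those plus contacts within each interval, pairs at least 20 kb apart. As fixed before the data were examined, 23 bins under 0.5 in any library were left out, 16 of them between Kcnj2 and Sox9. Several lay where coverage placed sequence in another order. For insulation and viewpoints, where no such rule had been fixed, bins under 0.05 and their neighbours were left out, 8 bins, chosen after the data were seen. The insulation score used KR values and a 200 kb window. Viewpoints were 30 kb windows. Expected contact was each library's own mean at each distance, taken over blocks of 3 by 3 bins for pairs of places.

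Sox9 and Kcnj2 were placed in the bins 112640001 to 112650000 and 110920001 to 110930000 from general knowledge of mm9, not from the deposited files, and no mm9 annotation was used to check this. Gene neighbours came from RefSeq (GRCm38), and none of its coordinates were used. In BorKnockIn the Sox9 window was moved by 1 bin to follow its shifted coordinates. Flank viewpoints at other promoters, planned before the data were examined, were not run, since mm9 positions of those genes were not used here. The named regions fixed beforehand were the depleted bins, fitted breakpoints and lowest insulation positions, plus in each library the 5 highest and 5 lowest pairs of 50 kb bins at least 200 kb apart with at least 20 contacts, in the library or as the median of the others. Pairs with fewer than 100 contacts are not described singly. The distal site, the step positions and the pairs of places were chosen after the data were seen.

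The planned comparison against BorKnockIn and InvIntra assumed that both kept the boundary in place. Coverage showed otherwise for BorKnockIn, so ratios to both are given and InvIntra carries the comparison. On simulated maps with known answers, shifts and mirrors were found with an error of 0.0 kb (6 maps), breakpoints with 0 kb (3 maps), a change of cross contacts within 0.003 (4 maps) and of insulation within 0.03 on the log2 scale (4 maps). These maps followed the same coverage profile and distance decay that the fits assume, and held no domains. They check the calculation and do not give the error on the deposited maps. Alternatives were KR values, thinned depth, distance, window, interval and which bins were left out.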

Results

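Chromatin contacts across the Kcnj2 and Sox9 locus of the mouse were measured by capture Hi-C, in which ligated DNA fragments from a chosen region are enriched and read pairs count contacts between places. The tissue was limb buds of E12.5 embryos. Sox9 encodes a transcription factor needed for cartilage formation, and Kcnj2 encodes an inward rectifier potassium channel. There were 8 homozygous mutants with 1 library each: ∆BorC1, ∆BorC1-2, ∆BorC1-4 and ∆CTCF (the deletion libraries), BorKnockIn, InvC, InvIntra and InvC∆Bor. The wildtype library and the remaining mutant that the series describes were not analysed here. The maps covered chromosome 11 from 109010001 to 114880000 (mm9) in 587 bins of 10 kb. InvC∆Bor was the shallowest library with 3056502 raw contacts and ∆BorC1-4 the deepest with 9045698, a 2.96-fold range. The others held 4901143 (∆BorC1), 6409072 (∆BorC1-2), 4449078 (∆CTCF), 5944448 (BorKnockIn), 4938928 (InvC) and 6234950 (InvIntra). With 1 library per genotype no test was possible, and every interval below covers counting error only.

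Bin coverage was examined to see what sequence each library held and in which order. The bin at chromosome 11, 111390001 to 111400000, between Kcnj2 and Sox9, was almost empty in the 4 deletion libraries, with 4 contacts in ∆BorC1, 0 in ∆BorC1-2, 8 in ∆BorC1-4 and 1 in ∆CTCF. With a limit of 3 counts, the 0 in ∆BorC1-2 allows a share of up to 4.68e-05% of that library's contacts. InvIntra had 28151 contacts in this bin, which is called the boundary here. In the RefSeq gene order (assembly GRCm38) 1 protein-coding model, Gm11677, lies between Kcnj2 and Sox9, Kcnj16 precedes Kcnj2 and Slc39a11 follows Sox9. InvC∆Bor had 131 contacts in the bin at 112500001 to 112510000, where InvC had 20049.

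By coverage, the 4 rearranged libraries had other sequence at the same coordinates. From 111460001 to 112410000 the coverage of each deletion library correlated with that of the other deletion libraries at r of 0.995 to 0.998 across bins, which are not independent replicates. BorKnockIn reached 0.0911 at the same positions and 0.912 after a shift of -19.0 kb. InvC went from -0.0345 to 0.901, InvC∆Bor from -0.0350 to 0.912 and InvIntra from 0.0642 to 0.881 when the profile was read in mirrored order. To the right of the edited interval BorKnockIn was shifted by -11.5 kb, a fitted net gain of 7.5 kb between the shifted parts. In windows of 300 kb the shift ran from -10.0 to -13.5 kb on the right. Inside the interval it ran from -18.0 to -20.0 kb, so the net gain is approximate. The fitted mirror put the boundary bin at 112.50 Mb in InvC and InvC∆Bor. The mirror of InvIntra was displaced by 18.5 kb against that of InvC. Positions in these 4 libraries are therefore those of the deposited maps, and BorKnockIn, taken as a library with an intact boundary before the data were examined, lacked about 19.0 kb at the original site. No inverted order fitted the deposited maps better, with a gain in log-likelihood of 0 per 1000 contacts in all 8 libraries. With only pairs at least 200 kb apart, all 8 preferred an inversion left of Kcnj2, away from the edits, by 2.38 (InvC∆Bor) to 4.11 (∆CTCF) per 1000 contacts.

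**Figure D1:**
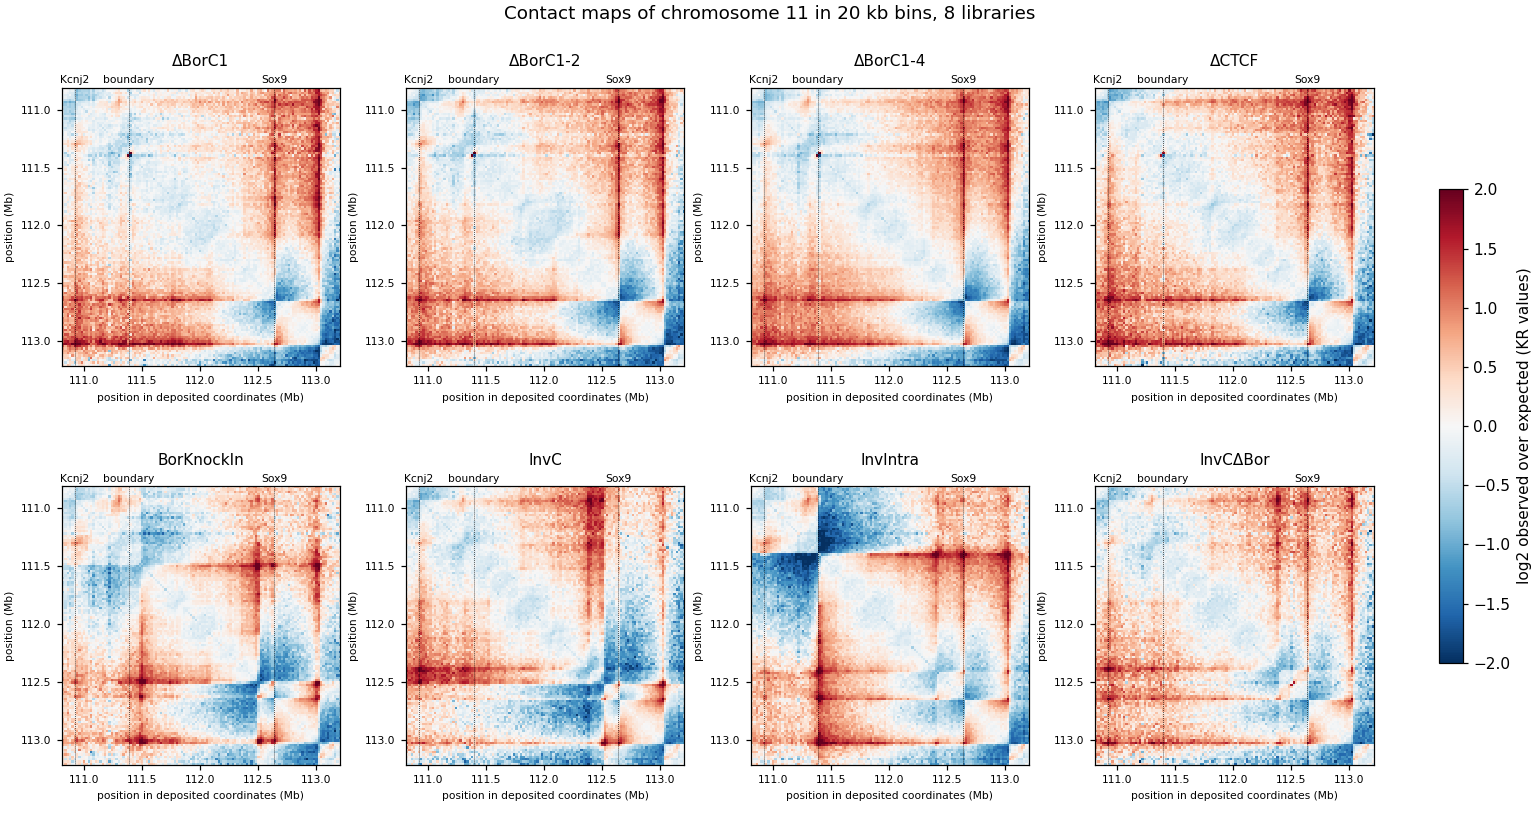
Contact maps of the 8 libraries in 20 kb bins, with position in deposited coordinates (Mb) on both axes and log2 observed over expected KR values as colour; dotted lines mark the bins of Kcnj2, the boundary and Sox9. InvIntra shows depleted contacts across the boundary, and BorKnockIn and InvC show such a depletion near 112.49 Mb, while isolated saturated pixels on the diagonal lie beside bins with almost no contacts.

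To see how far the Kcnj2 side and the Sox9 side stay separate without the boundary, contacts between them were counted. They were more frequent in the deletion libraries than in InvIntra, which held contacts in the boundary bin and was planned as a comparator before the data were examined. Contacts across the boundary made up 11.9% of those between Kcnj2 and Sox9 in InvIntra (exact 95% interval 11.8 to 11.9). They made up 19.6% in ∆BorC1 (19.5 to 19.7), 20.3% in ∆BorC1-2 (20.2 to 20.4), 19.8% in ∆BorC1-4 (19.8 to 19.9) and 21.3% in ∆CTCF (21.2 to 21.4). Their ratios to InvIntra were 1.65, 1.71, 1.67 and 1.79, and their ratios to BorKnockIn 1.32, 1.37, 1.34 and 1.43. BorKnockIn itself held 14.8%, 1.25 times InvIntra. InvC held 22.4% and InvC∆Bor 22.1%. With 400 kb on each side, the highest library lay 2.23-fold above the lowest at the boundary. At 194 positions in the unedited flanks this ratio had a median of 1.11 and reached at most 1.22. The ratio of ∆CTCF to ∆BorC1-4 was 1.07 between Kcnj2 and Sox9 and 1.05 with 400 kb on each side, while at the flank positions the ratio of these libraries ran from 0.920 to 1.00, with a median of 0.955. These comparisons rest on 1 library, InvIntra, whose neighbouring sequence was inverted. The labels of the deletion libraries also name C1 to C4 or CTCF, and none of these libraries is labelled as lacking the boundary alone. The difference from InvIntra therefore cannot be assigned to the boundary alone. Distances in the deletion libraries were read from map coordinates, so the lost sequence brings the sides closer than counted. No correction was made for this, here or below.

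The insulation score, log2 of the mean contact across a position over the library's mean, was -1.98 at the boundary in InvIntra. It was -0.39 in ∆BorC1, -0.39 in ∆BorC1-2, -0.43 in ∆BorC1-4, -0.29 in ∆CTCF, -0.43 in InvC and -0.46 in InvC∆Bor, while BorKnockIn had -0.74. At 276 flank positions the SD over the 8 libraries had a median of 0.03 and a maximum of 0.08. The Sox9 side ended at 113.03 Mb in the deletion libraries, where the score was -1.46 in ∆BorC1, -1.54 in ∆BorC1-2, -1.52 in ∆BorC1-4 and -1.47 in ∆CTCF. There it was -1.32 in InvIntra, -1.21 in InvC and -1.27 in InvC∆Bor. At the Sox9 bin (112640001 to 112650000) the score was lower in the deletion libraries, from -0.98 in ∆BorC1 to -1.18 in ∆CTCF, than in InvIntra at -0.77. InvC∆Bor, without the boundary, also had -0.77, and InvC had -0.36, so the difference did not follow the boundary alone. The window there reaches into sequence inverted in InvIntra, InvC and InvC∆Bor. At the flank positions the range over the 8 libraries reached 0.27.

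**Figure D2:**
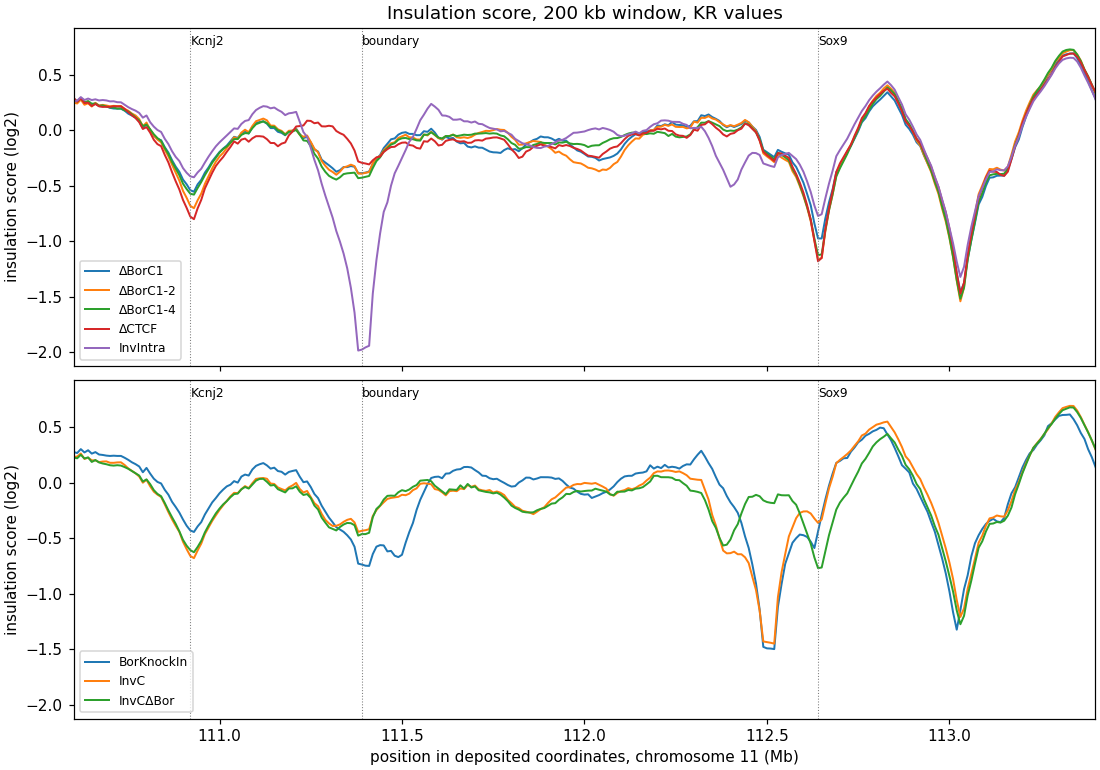
Insulation score (log2, 200 kb window, KR values) along chromosome 11 in deposited coordinates (Mb), with 1 line per library. InvIntra falls to -1.98 at the boundary, and BorKnockIn and InvC fall to -1.48 and -1.43 at 112.49 Mb.

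The deletion libraries were set side by side in the order of their labels to ask where insulation differed; the labels do not say whether ∆CTCF carries the deletions of ∆BorC1-4. ∆CTCF lost a dip to the left of the boundary that the other deletion libraries kept: at 111.31 Mb its score was 0.03, against -0.34 in ∆BorC1, -0.38 in ∆BorC1-2 and -0.43 in ∆BorC1-4. The change of 0.47 from ∆BorC1-4 exceeded the largest change between these libraries in the flanks, 0.16. ∆BorC1-2 rose by 0.21 over ∆BorC1 at 111.76 Mb (flank maximum 0.08), and its score changed by -0.14 at 111.95 Mb. ∆BorC1-4 rose by 0.26 over ∆BorC1-2 at 112.06 Mb (flank maximum 0.09), where ∆BorC1-2 had the lowest score of the deletion libraries, -0.36, against -0.25 in ∆BorC1, -0.19 in ∆CTCF and -0.10 in ∆BorC1-4. At 112.26 Mb the score of ∆BorC1-4 changed by -0.09 from ∆BorC1-2. These positions were picked as the largest changes after the scores were seen. The deletions named by C1 to C4 were not resolved in the coverage of 10 kb bins.

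Sox9 and Kcnj2 both reached further across the deleted boundary in the deletion libraries than across the boundary in InvIntra. These libraries' labels also name C1 to C4 or CTCF, so the difference cannot be assigned to the boundary alone. Of the contacts of a 30 kb window at Sox9, 4.35% lay between Kcnj2 and the boundary in InvIntra (4.19 to 4.52), against 6.81% in ∆BorC1 (6.59 to 7.04), 7.97% in ∆BorC1-2, 8.03% in ∆BorC1-4 and 8.36% in ∆CTCF (8.10 to 8.62). BorKnockIn had 4.36% (4.17 to 4.55), which could not be separated from InvIntra at this depth with a 30 kb window; with a 10 kb window its ratio to InvIntra was 0.842. Of the contacts of Kcnj2, 14.5% lay between the boundary and Sox9 in InvIntra (14.2 to 14.8), 18.5% in BorKnockIn, 23.1% in ∆BorC1, 25.4% in ∆BorC1-2, 23.4% in ∆BorC1-4 and 28.6% in ∆CTCF (28.2 to 29.0). Contacts between Kcnj2 and Sox9 themselves stood at 2.02 times the value expected for their distance in InvIntra (interval 1.78 to 2.30). They stood at 3.59 in ∆BorC1 (3.21 to 4.00), 4.63 in ∆BorC1-2, 4.25 in ∆BorC1-4 and 5.65 in ∆CTCF (5.17 to 6.17). In BorKnockIn they stood at 1.68 (1.44 to 1.95). Kcnj2 and the 111.31 Mb site stood at 1.21 in ∆CTCF (1.08 to 1.34) and at 1.69 in ∆BorC1-4 (1.59 to 1.78). No flank viewpoints were computed, so the spread between libraries of these shares was not measured.

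**Figure D3:**
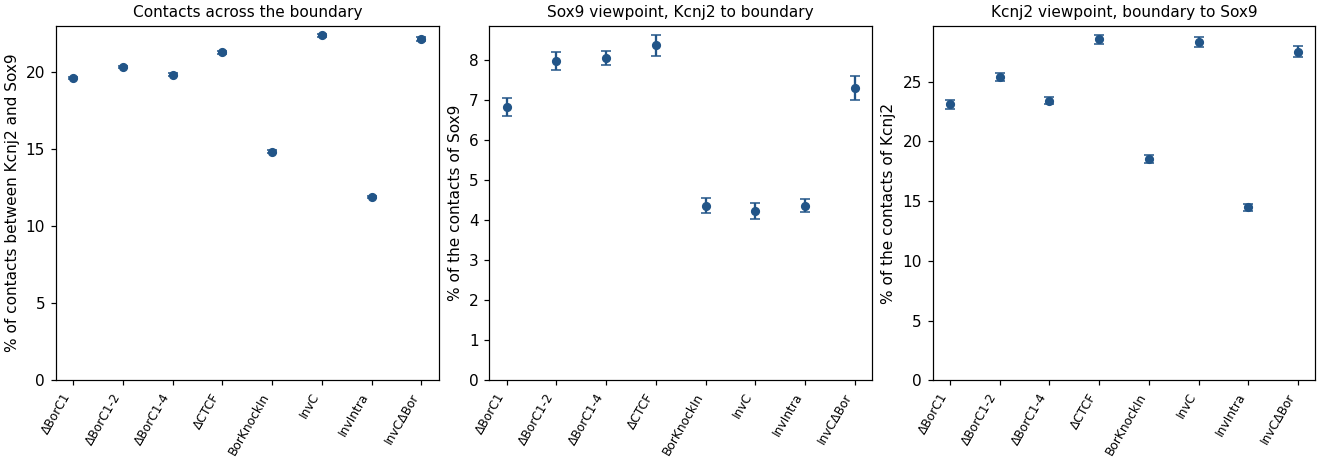
Percent of contacts across the boundary, of Sox9 contacts beyond the boundary and of Kcnj2 contacts beyond the boundary in each library (points), with exact 95% intervals for counting error (bars). InvIntra is lowest for contacts across the boundary (11.9%) and for Kcnj2 (14.5%), and InvC, InvIntra and BorKnockIn lie together for Sox9.

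BorKnockIn was compared with the deletion libraries to ask whether a boundary placed within the Sox9 side divides it. At 112.49 Mb its insulation score was -1.48, 1.29 below the median of the deletion libraries (a difference of -1.29), whose scores ran from -0.18 to -0.21. These scores were read at the same deposited coordinate, without following the shift of BorKnockIn. InvC had -1.43 at that coordinate, InvIntra -0.30 and InvC∆Bor -0.16. Contacts across the site at 112.50 Mb made up 14.4% in BorKnockIn (14.3 to 14.5), against 27.1% in ∆BorC1 and 25.0% in ∆CTCF. Sox9 directed 38.2% of its contacts to the interval between the original boundary and Sox9 in BorKnockIn, against 51.8% in ∆BorC1 and 47.7% in ∆CTCF. At Sox9, read 1 bin to the left to follow the shift of BorKnockIn, the score was -0.59. Near the original site BorKnockIn was lowest at 111.41 Mb, with -0.75, and its difference from ∆BorC1 was largest at 111.49 Mb, where it had -0.67 and ∆BorC1 had -0.02 at the matching sequence.

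InvC and InvC∆Bor share the inverted order and differ by the boundary, which asks what the boundary does in its new place next to Sox9. Contacts across 112.50 Mb, again with 400 kb on each side, rose from 13.7% in InvC (13.5 to 13.8) to 25.4% in InvC∆Bor (25.2 to 25.6). The ratio was 1.86 (1.83 to 1.88), and the score at 112.49 Mb went from -1.43 to -0.16. The share of Sox9 contacts between Kcnj2 and the original boundary position was 4.22% in InvC (4.03 to 4.41) and 7.30% in InvC∆Bor (7.00 to 7.60), a ratio of 1.73 (1.63 to 1.84). Sox9 had 33.5% of its contacts between the original boundary position and itself in InvC and 42.7% in InvC∆Bor. The share of Kcnj2 changed less. Of its contacts, 28.3% lay between the original boundary position and Sox9 in InvC and 27.5% in InvC∆Bor, a ratio of 0.971 (0.949 to 0.993). Kcnj2 and Sox9 stood at 1.93 times the expected contact in InvC (1.65 to 2.24) and 3.58 in InvC∆Bor (3.15 to 4.05). At the original boundary position the scores were -0.43 in InvC and -0.46 in InvC∆Bor.

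Pairs of 50 kb bins that differed most from the median of the other libraries mostly had an end near an edited place in BorKnockIn, InvC and InvIntra, where 23 of the 30 pairs held at least 100 contacts. Positions are bin starts in deposited coordinates, where by coverage the rearranged libraries hold different sequence. The 5 lowest pairs of BorKnockIn, with 776 to 1175 contacts each, lay on either side of the 112.49 Mb site, and the log2 ratio was -1.41 for 112.36 with 112.61 Mb. Its highest ratio was 1.56, for 111.46 with 112.46 Mb. InvC had -1.68 for 112.36 with 112.56 Mb and 1.43 for 112.51 with 113.01 Mb. Another 4 of its 5 highest pairs joined bins left of Kcnj2 to 112.36 or 112.46 Mb. InvIntra had -1.67 for 111.26 with 111.46 Mb, across the boundary, and 1.18 for 110.36 with 111.36 Mb, where 3197 contacts were counted. The median of the others for the latter pair was 712 contacts. The 50 kb bin at 111.36 Mb holds the boundary bin, which was almost empty in the deletion libraries. The ratio is thus partly against libraries that lack sequence there, and cannot be read as a gained contact. InvC∆Bor had 1.03 for 110.36 with 112.36 Mb (1054 contacts). In the deletion libraries 36 of 40 pairs held fewer than 100 contacts. Of the other 4, ∆BorC1-2 had 0.92 for 110.56 with 113.11 Mb and ∆BorC1-4 had 1.00 for 110.56 with 114.26 Mb, each with fewer contacts than the following pairs. ∆BorC1 had 0.80 for 111.76 with 112.61 Mb (1554 contacts), and ∆BorC1-2 had 0.87 for 112.06 with 112.61 Mb (2859 contacts), where the Sox9 bin lies within the bin at 112.61 Mb.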

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

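The last 2 settings of the share (no bins left out, fewer bins left out), all settings of the steps at 111.31, 111.76 and 112.06 Mb, the 400 kb knock-in window, no bins left out for scores and viewpoints, thinned scores and the reference order were chosen after seeing the data. Summaries over the 4 deletion libraries were also chosen then. Among 193 alternative values, no result with a called direction turned. The Sox9 shares of BorKnockIn and InvC over InvIntra, not separable with the 30 kb window, moved beyond their counting intervals: BorKnockIn to 0.932 (KR), 0.842 (10 kb) and 0.925 (no bins left out), InvC to 1.16 (10 kb) and 0.894 (no bins left out). The cause of each move was not tested. The deletion median over InvIntra for contacts across the boundary, 1.69, became 1.62 with KR values, 1.68 beyond 100 kb, 1.56 as mean observed over expected, 2.14 with 400 kb intervals, 1.60 with no bins and 1.67 with fewer bins left out. ∆CTCF over ∆BorC1-4, 1.07, became 1.06, 1.11, 1.13 and 1.05 under the KR, 100 kb, observed over expected and 400 kb settings. BorKnockIn over InvIntra ran from 1.23 to 1.65. The deletion median minus InvIntra for insulation, 1.59, became 1.89 (100 kb), 1.29 (400 kb), 1.49 (raw), 1.65 (no bins left out) and 1.46 (thinned raw). The knock-in difference, -1.29, became -1.56, -0.91, -1.24 and -1.22 with 100 kb, 400 kb, raw and thinned raw. The step of ∆CTCF, 0.47, became 0.54 (100 kb) and 0.36 (400 kb). The step of ∆BorC1-2 at 111.76 Mb, 0.21, ran from 0.14 to 0.24 over the settings. That of ∆BorC1-4 at 112.06 Mb, 0.26, ran from 0.19 to 0.26. The Sox9 ratio, 1.84, became 2.06 (10 kb), 1.71 (50 kb) and 1.73 (no bins left out), and the Kcnj2 ratio, 1.69, became 1.77 (KR), 1.64 (50 kb) and 1.63 (no bins left out). InvC∆Bor over InvC for Sox9, 1.73, became 1.62 with KR values. Bins depleted in all 3 ∆BorC libraries rose from 4 to 9 under 0.7. The inversion fit gained up to 4.11 per 1000 contacts with pairs beyond 200 kb, in all 8 libraries and away from the edits, and at least 11.4 in reference order, which follows from the construction, since the deposited order fitted best and the reordering undid it. Of 150 alternative values for single libraries, 104 moved beyond their interval or flank spread and 46 did not. Depth limits pairs of places: Kcnj2 with Sox9 rests on 168 contacts in InvC and 242 in InvIntra.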

Other observations

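All tests in this part were chosen after the patterns were seen; for depth, balancing and sequence loss at 111.31 Mb the bounds were set before the values that decide them were computed.

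Kcnj2 and the edge at 113.03 Mb stood at 4.33 times the expected contact in ∆BorC1 (3.83 to 4.87) and 4.65 in ∆CTCF. The values were 4.76 in ∆BorC1-2, 4.07 in ∆BorC1-4 (3.74 to 4.43) and 3.73 in InvC∆Bor (3.22 to 4.29). They were lower in InvIntra with 2.49 (2.17 to 2.85), InvC with 2.23 and BorKnockIn with 1.76 (1.44 to 2.12). The contact of Sox9 with that edge ran from 2.01 to 2.25 times the expected in the deletion libraries, within or near the interval of InvIntra (2.08 to 2.33). It was 2.92 in InvC (2.76 to 3.10), 2.48 in BorKnockIn (2.33 to 2.63) and 2.10 in InvC∆Bor (1.91 to 2.29).

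Coverage of the rearranged libraries departed from that of the deletion libraries inside the edited interval. Noise of capture or library would also lower the correlation left of the boundary. Over that side as a whole, the lowest value of the 4 libraries was 0.983. In windows of 300 kb there, InvC fell as low as 0.955. Maps drawn in the order of the rearranged chromosome may account for it: mirroring or shifting gave a correlation of at least 0.881 in each of the 4 libraries. No read-level check was possible.

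The dip at 111.31 Mb, present in the 3 ∆BorC libraries and absent in ∆CTCF, did not come from balancing: the change was 0.45 on raw contacts, above a bound of 0.3. It was also 0.45 after thinning, above the same bound. Thinning at an even rate leaves the expected score unchanged, so it covers only counting noise at lower depth. Other differences that go with depth were not tested. Loss of sequence from the neighbouring bin stays open. Relative to neighbouring bins, contacts within that bin changed by -0.12 on the log2 scale against -0.28 for its contacts farther away. This met its bound, but by less than the SD of 0.15 over flank bins. That SD was taken without setting bins against their neighbours, so it is only a rough guide. Removal of a site by the deletions in ∆CTCF may explain its higher score, as a hypothesis, since its label names CTCF. No CTCF binding was measured here.

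The low boundary score of InvIntra could have come from its inversion. InvC and InvC∆Bor join inverted sequence to the Kcnj2 side without the boundary, and the lower of their scores there was -0.46 against -1.98, which argues against the inversion as the whole cause. A share of the difference due to the exact junction stays open.

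In BorKnockIn, 111.49 Mb was picked for its largest difference from ∆BorC1. Whether its low score there is a dip apart from the lowest score of -0.75 at 111.41 Mb, beside the lost sequence, was not tested. A hypothesis for the low score at 111.49 Mb is a sequence that libraries with C1 in their label lack. If so, the mirrored libraries may carry it at 112.39 or 112.41 Mb. Between 111.69 and 112.57 Mb, an interval that leaves out the original boundary position and Sox9, the lowest scores lay within 10.0 kb of this in InvIntra (112.40 Mb, score -0.51) and InvC∆Bor (112.38 Mb, score -0.56). In InvC the lowest score was 130.002 kb away, at its own relocated boundary, so the 200 kb window could not decide. With a 100 kb window, tried afterwards, the local minimum nearest the predicted place lay at 112.38 Mb, with -0.77. It was picked for its nearness, so its position cannot decide either. ∆CTCF, without C1 in its label, had no such low score either (-0.11 at 111.50 Mb), and the labels do not say whether its deletions include C1.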
